A study of Caenorhabditis elegans with 15 samples.

How the data were processed

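The material was poly(A) RNA of whole Caenorhabditis elegans, extracted with QIAzol from about 1000 worms per library according to the labels' protocols, and sequenced as read pairs of 150 nucleotides. The 15 libraries fall into 3 groups of 5 by their genotype label. Wild type is the laboratory strain N2. ACP7 OE carries the coding sequence of F21A3.11, a secreted phosphatase called ACP7, behind the promoter of ges-1, a gut esterase gene active in the intestine. A trans-spliced reporter, WormScarlet, and the 3 prime untranslated region of unc-54, a muscle myosin gene, follow it. ACP7-7A OE carries the same construct with a phosphatase-inactive form. The labels name a single strain for each construct.

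The authors deposited a single table of gene counts, with 15 columns of libraries and 46929 genes, made with featureCounts 2.0.6 per the file headers. Trim Galore, STAR and the genome build WBcel235 are named in the submitters' processing notes, with no version for either tool. The settings for strand, for reads that align to several places and for mates of a pair are not given in the sources used here. The deposited counts are whole numbers with no normalization. Between 81.3% and 86.1% of the values from 5 to 39 in a library were even numbers, so the mates of a pair appear to have been counted separately, and a table with every count halved and rounded down was analysed as an alternative chosen after seeing the data. Every column belonged to a sample in the labels. Gene coordinates are those in the file (WBcel235). Symbols came from a RefSeq gene table of that organism, which matched 46925 of the gene identifiers, and from Ensembl release 115. Without strand, reads of overlapping genes on opposite strands cannot be told apart, and reads of near-identical paralogs may have been split or dropped.

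Library totals ran from 39050495 to 58077047 counts. Differences were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 (robust fit), after filterByExpr on the groups had kept 15725 genes and with TMM scaling. All 15 libraries and 3 groups entered a single fit and shared an estimate of spread, with a common biological coefficient of variation of 0.21. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene is said to have risen or fallen at an adjusted p under 0.05. Levels are given as TMM-scaled counts per 1e6 counts (CPM), computed here from the deposited counts, as mean ± SD over 5 libraries. Log2 fold changes are given with the standard error (SE) implied by the test. Where a group held no count of a gene, a lower bound was computed against 3 counts over the whole group. Where it held 1 to 3 counts, the ratio is given with an exact 95% interval. Such intervals and bounds cover counting error only, and treat counts as independent. With mates counted separately the intervals are too narrow and the bounds too high.

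The 30 gene lists, the rule for naming genes, the tests and most other settings were written before the data were examined. F21A3.11 was left out of the acid phosphatase list and unc-54 out of the muscle list, because the construct adds reads to both. The names written for the mitochondrially encoded list did not match the table's names, and the list was completed by chromosome, giving 12 protein-coding genes. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and adjusted over the 30 lists of a comparison. The same test with an estimated correlation, and fry for direction and for change in either direction, were run as alternatives. The number of members past the threshold is given over all genes, and for some lists also adjusted over the list alone. Named genes are F21A3.11, ges-1 and unc-54; per comparison the 10 highest and 10 lowest log2 fold changes among genes past the threshold with an average log2 CPM of at least 1 and no overlap between the CPM of the groups; per list and comparison up to 4 members past the threshold with the smallest p, or 2 members where none passed; and the 5 highest and 5 lowest genes by fold change between the constructs among those changed the same way in ACP7 OE against both other groups. A gene named outside that rule is marked as chosen after its values were seen.

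Comparisons that share libraries share chance values. The shared counts and the correlation of fold changes were therefore set beside 20 simulations of unchanged groups, beside the overlap of independent lists of the same sizes, and beside 20 splits of the shared libraries into sets of 2 and 3. The correlation was planned across all genes tested. It is also given for 2 other sets of genes chosen after seeing the data: all but F21A3.11 and WormScarlet, and genes with an average log2 CPM of at least 1. The procedure was tested on simulated data drawn from the gene means, spread and library sizes of these libraries, with 200 genes of average log2 CPM above 1 changed in ACP7 OE. A further list of genes was given a smaller common rise there, and its genes are counted neither as recovered nor as unchanged below. Of the simulated genes, 15410 passed the expression filter. In ACP7 OE against wild type the test recovered 71 of 100 genes changed 1.5-fold, 46 of 50 changed 2-fold and all 50 changed 4-fold. It made 8 false calls among the 15185 unchanged genes that passed the filter, and 0 calls in the simulated comparison of ACP7-7A OE with wild type, where no gene was changed.

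The other settings fixed in advance were RLE and upper-quartile scaling, no expression filter, a filter of 50 reads in 5 libraries, DESeq2 1.42.0, limma-voom, fits of the compared groups alone, the replicate number as a block, 1 surrogate variable from sva 3.50.0, library sizes without mitochondrial, rRNA and histone genes, stricter thresholds, and leaving out each library in turn. Leaving out 3 libraries together (ACP7-7A OE 1 and 2 and wild type 5) was added after seeing the data, because they stood apart within their groups. The group labels were also exchanged among libraries in 100 splits per comparison. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical in part.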

Results

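The series asks how overexpression of ACP7 from the intestine alters the transcriptome of C. elegans, compared with wild-type N2 animals and with animals that overexpress a phosphatase-inactive form, ACP7-7A. Poly(A) RNA of whole worms was counted per gene in 5 libraries of each group. The totals were 39050495 to 49452773 counts in wild type, 39180648 to 58077047 in ACP7 OE and 41696722 to 50869260 in ACP7-7A OE. Between 17186 and 18610 genes had at least 1 count in a library. Ribosomal RNA genes took 2.82% ± 0.42 of the counts in wild type, 2.07% ± 0.65 in ACP7 OE and 1.60% ± 0.39 in ACP7-7A OE (SD, n = 5 each). Vitellogenin genes, which encode yolk proteins, took 8.58% ± 0.32, 9.01% ± 0.55 and 8.56% ± 0.47.

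Some libraries stood apart from others of their own group. ACP7-7A OE libraries 1 and 2 had sperm-list medians of 1.04 and 0.93 log2 CPM, against 2.80, 2.57 and 2.79 in libraries 3 to 5. Their cuticle collagen medians were 1.47 and 1.46, against 2.38, 2.71 and 2.82. Wild-type library 5 had a sperm-list median of 1.62, against 2.09 to 2.2 in the other wild-type libraries, and an intestine-list median of 5.36, against 5.98 to 6.18. The first principal component of the 2000 most variable genes held 33.5% of the variance. On it the ACP7 OE libraries lay between 31.5 and 46.8, wild type between -30 and -16, ACP7-7A OE libraries 1 and 2 at -40.9 and -44.0, and ACP7-7A OE libraries 3 to 5 between -9.3 and -1.9.

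F21A3.11, the overexpressed gene (chromosome V, 15530783 to 15533212, minus strand), stood at 15 ± 1.52 CPM in wild type, 610 ± 29.8 CPM in ACP7 OE and 1360 ± 229 CPM in ACP7-7A OE (SD, n = 5 each). It rose 40.6-fold in ACP7 OE (log2 fold change 5.34, SE 0.11, edgeR adjusted p = 7.1e-17) and 90.7-fold in ACP7-7A OE (log2 fold change 6.5, SE 0.12, adjusted p = 7.3e-18). The counts of this gene include reads of the endogenous locus and of either transgene. Its level was lower in ACP7 OE than in ACP7-7A OE by a log2 fold change of -1.16 (SE 0.09, adjusted p = 1.4e-07). The constructs thus differed in RNA dose, besides the difference in activity given by their design, which was not measured here. The reporter WormScarlet had 0 counts in wild type, 869 ± 61.0 CPM in ACP7 OE and 2030 ± 372 CPM in ACP7-7A OE, with a log2 fold change between the constructs of -1.22 (SE 0.12, adjusted p = 5.7e-05). Within ACP7-7A OE the F21A3.11 level was 1070 and 1160 CPM in libraries 1 and 2 and 1500 to 1550 CPM in libraries 3 to 5.

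ges-1, the source of the promoter (chromosome V, 1427653 to 1432137, minus strand), had 43.8 ± 2.98 CPM in wild type and 44.2 ± 5.30 CPM in ACP7 OE. It fell in ACP7-7A OE to 34.6 ± 0.86 CPM (log2 fold change -0.34, SE 0.08, adjusted p = 0.011). unc-54, the source of the 3 prime untranslated region (chromosome I, 14855901 to 14863482, minus strand), had 1180 ± 130 CPM in wild type, 1060 ± 223 CPM in ACP7 OE and 1940 ± 576 CPM in ACP7-7A OE. The difference of ACP7-7A OE from wild type did not pass (log2 fold change 0.72, SE 0.20, adjusted p = 0.052). unc-54 was lower in ACP7 OE than in ACP7-7A OE (log2 fold change -0.88, SE 0.20, adjusted p = 0.018), a call lost when ACP7 OE library 2, 3 or 4 was left out (adjusted p = 0.053, 0.054 and 0.056).

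**Figure D1:**
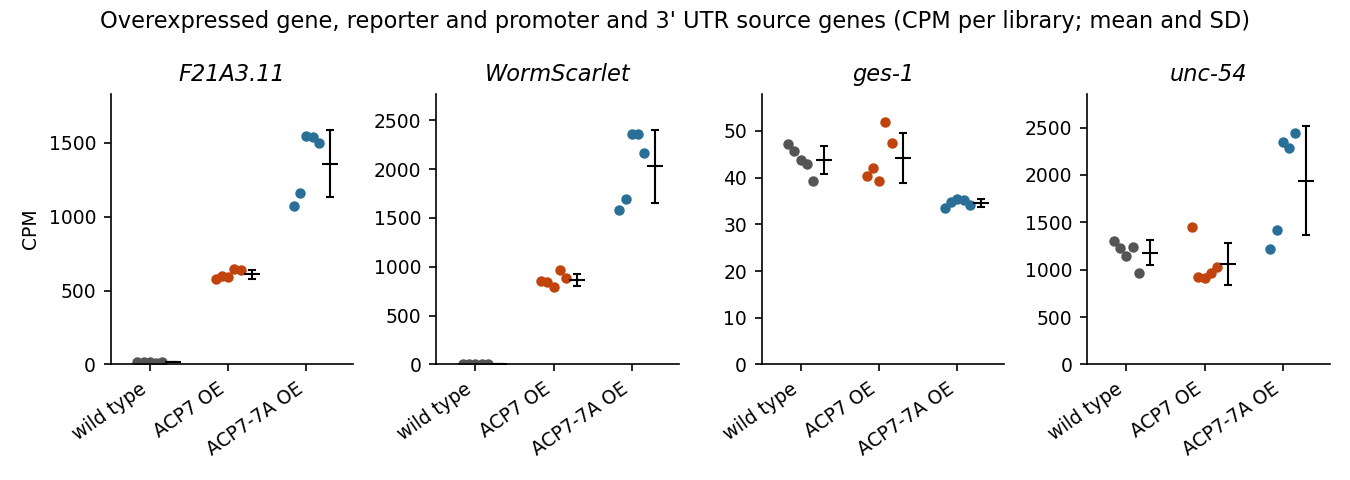
CPM of F21A3.11, WormScarlet, ges-1 and unc-54 in each of the 15 libraries (points, by group; vertical axes in CPM from 0), with the mean and SD of each group of 5 (bars). F21A3.11 averages 15, 610 and 1360 CPM in wild type, ACP7 OE and ACP7-7A OE, and ACP7-7A OE libraries 1 and 2 lie below the other ACP7-7A OE libraries for F21A3.11, WormScarlet and unc-54.

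Against wild type, ACP7 OE animals had a set of transcripts that were at or near 0 elsewhere. clec-197, a C-type lectin gene (chromosome IV, 17345553 to 17346699), had 0 counts in wild type and 10.4 ± 2.75 CPM in ACP7 OE, at least 764-fold higher (adjusted p = 6.5e-05). F59B2.12 rose from 0.0576 ± 0.0814 to 14 ± 3.09 CPM, F26D2.16 from 0.0861 ± 0.0769 to 7.87 ± 2.54 CPM, and the trypsin-like protease gene try-8 from 0.143 ± 0.0557 to 6.17 ± 2.08 CPM (adjusted p = 2.1e-05, 2.7e-06 and 4.9e-05). try-8 overlaps try-11, a tested gene, on the other strand. C38D9.2 fell 15.5-fold, from 153 ± 21 to 9.88 ± 0.514 CPM (adjusted p = 3.1e-20), and the mitochondrially encoded ATP6 fell by 0.66 on the log2 scale (adjusted p = 2.1e-08).

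In all, 422 of 15725 genes changed in ACP7 OE against wild type, 233 of them higher and 189 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). An absolute log2 fold change of at least 1 was reached by 184 of the higher and 22 of the lower genes. Of the higher genes, 108 averaged under 1 CPM over all libraries. Of the genes named by size, fbxa-195, an F-box gene annotated as a pseudogene (chromosome V, 1434339 to 1435804), had 0 counts in wild type, 22.8 ± 2.46 CPM in ACP7 OE and 30.8 ± 2.89 CPM in ACP7-7A OE, at least 1610-fold and 2210-fold higher. It lies 2202 bp from ges-1 on the side of its promoter. Y51A2D.8 rose from 0.181 ± 0.0989 to 6.11 ± 2.31 CPM (adjusted p = 0.00027). The sperm gene spe-46 rose 3.30-fold (adjusted p = 0.010). ant-1.4, which encodes an adenine nucleotide translocator, had an adjusted p of 0.032 that reached 0.1 with single libraries left out, and its call was lost without any of 9 libraries.

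Among the lower genes, F56A4.3 (chromosome V, 2453414 to 2456147) fell 6.95-fold from 46.7 ± 1.98 CPM (adjusted p = 6.7e-12), F15D4.5 (chromosome II, 13245376 to 13247774) fell 4.67-fold from 28.4 ± 2.93 CPM (adjusted p = 1.5e-13), and C38D9.13, beside C38D9.2 on chromosome V, fell 4.90-fold (adjusted p = 5.4e-07). F15D4.6, beside F15D4.5, fell 2.73-fold (adjusted p = 1.2e-05). clec-209 and F56A4.2 had nearly equal levels in every group, 8.45 ± 0.388 and 8.52 ± 0.478 CPM in wild type and 3.43 ± 0.694 and 3.54 ± 0.693 CPM in ACP7 OE, and whether they share reads was not examined. dhs-26, a dehydrogenase gene on the X chromosome, fell 3.80-fold (adjusted p = 0.011), and it overlaps ZK816.1 on the other strand. T22B7.7 had a log2 fold change of -1.29 (adjusted p = 0.023, or 0.082 without ACP7 OE library 3). cyp-14A4 had a log2 fold change of -1.12 (adjusted p = 0.043), and its call was lost without any of 8 libraries.

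Of the lysozymes, C-type lectins and saposin-like proteins, 32 of 176 tested members rose in ACP7 OE, 4 fell and 140 did not pass (45 and 7 adjusted over the list alone). clec-94 (0 counts in wild type) was at least 365-fold higher and clec-137 at least 258-fold higher. clec-208 and clec-207 had 2 counts each over the wild-type group, giving ratios of 504 (95% interval 139 to 4170) and 347 (95.8 to 2870). Of the 32 members that rose, 21 were higher in ACP7 OE than in both other groups by a log2 fold change of at least 3. A separate list of 13 male genes, chosen after seeing the data, summed to 2.92 ± 0.805 CPM in ACP7 OE, 1.5 ± 0.302 CPM in wild type and 1.72 ± 0.715 CPM in ACP7-7A OE (SD, n = 5 each). The lectin list was higher against other genes (adjusted p = 7.2e-13 with the preset correlation, adjusted p = 0.042 with an estimated correlation), with a median log2 fold change of 0.17 and a mean of 1.14. With its 9 members at 0 in 1 group set to their bound, the median was 0.17 and the mean 1.02. The insulin-like peptide gene ins-31 rose (log2 fold change 7.86, SE 0.66, adjusted p = 6.9e-08), and the other 21 tested insulin-like genes did not pass. ins-31 too was higher in ACP7 OE than in both other groups by a log2 fold change of at least 3. It thus belongs to the group of 97 genes near 0 outside ACP7 OE that is taken up below.

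Mitochondrially encoded genes were lower, with 8 of 12 falling, 0 rising and 4 not passing (10 lower and 1 higher adjusted over the list alone). The list was planned as a sign of RNA preparation (poly(A) selection). Whether preparation or expression differed was not tested. These genes took 1.58% ± 0.16 of the counts in wild type, 1.21% ± 0.05 in ACP7 OE and 1.43% ± 0.08 in ACP7-7A OE (SD, n = 5 each). ND2, ND4 and COX3, of respiratory complexes, fell by 0.58, 0.42 and 0.59 on the log2 scale. The list gave adjusted p = 2.2e-15 with the preset correlation and adjusted p = 0.085 with an estimated correlation. Of 20 basement membrane genes, 5 fell, including the laminin genes lam-1 and lam-2 (log2 fold changes -0.39 and -0.41, adjusted p = 0.00071 and 0.00047), and 15 did not pass (13 lower adjusted over the list alone; list adjusted p = 2.2e-08, or adjusted p = 0.34 with an estimated correlation). Of 19 lysosomal and digestive proteases, cpr-4, a cathepsin B-like protease, rose (log2 fold change 0.39, SE 0.08, adjusted p = 0.0083). asp-13 had an adjusted p of 0.017, lost without any of 4 libraries, and the other 17 did not pass (10 higher and 2 lower adjusted over the list alone; list adjusted p = 0.0058, or adjusted p = 0.60 with an estimated correlation). Without wild-type library 5 the protease list gave adjusted p = 0.059. Of 17 acid phosphatases, pho-11 fell (log2 fold change -0.58, SE 0.06, adjusted p = 1.2e-06) and 16 did not pass (list adjusted p = 0.015, or adjusted p = 0.43 with an estimated correlation).

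Of 85 sperm genes, 5 rose and 80 did not pass (19 higher adjusted over the list alone), with a median log2 fold change of 0.94. spe-18 had a log2 fold change of 1.38 (adjusted p = 0.014, or 0.056 without wild-type library 4) and nspd-9 of 2.01 (adjusted p = 0.014, or 0.054 without ACP7 OE library 1 or 3). The list gave adjusted p = 1.5e-15 with the preset correlation and adjusted p = 0.43 with an estimated correlation, and the sperm-list median was 2.61 to 3.37 log2 CPM in ACP7 OE libraries. Of 10 cytosolic heat shock genes, hsp-70 and hsp-16.2 passed (adjusted p = 0.042 and 0.046), each call lost without any of 9 libraries (list adjusted p = 0.0083, or adjusted p = 0.085 with an estimated correlation).

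No member passed among 14 molting, 50 transthyretin-like, 30 germline and oocyte, 14 early embryo, 16 body wall muscle or 23 neuron genes. Adjusted over the list alone, 5 molting genes were lower and no member of the other lists passed. These lists gave adjusted p = 0.0044, 0.029, 0.0044, 0.017, 0.0029 and 0.029, and adjusted p = 0.43, 0.60, 0.66, 0.43, 0.61 and 0.66 with an estimated correlation. Leaving out wild-type library 5 took the early embryo list to adjusted p = 0.12, and leaving out ACP7 OE library 1 took the germline and oocyte list to 0.087. The transthyretin-like list was lost without wild-type library 2, 3 or 4 (0.084, 0.13 and 0.090) or ACP7 OE library 1, 2 or 3 (0.061, 0.086 and 0.050), and the neuron list without wild-type library 1, 2 or 4 (0.081, 0.077 and 0.051) or ACP7 OE library 2 or 4 (0.059 and 0.072). In wild-type library 5 the muscle and neuron medians were 7.88 and 2.80 log2 CPM, against 8.39 to 8.54 and 3.23 to 3.33 in the other wild-type libraries. The germline and oocyte median was 0.10, and the medians of the other lists were negative, from -0.35 to -0.11. Of 14 pharynx genes pha-4 had an adjusted p of 0.041, lost without any of 6 libraries, and 13 did not pass (list adjusted p = 0.029, or adjusted p = 0.60 with an estimated correlation). The pharynx list was lost without wild-type library 1, 2 or 4 (0.074, 0.081 and 0.061) or ACP7 OE library 2 (0.063). Of 119 cytochrome P450 and UDP-glucuronosyltransferase genes, 1 rose and 3 fell (list adjusted p = 0.025, or adjusted p = 0.60 with an estimated correlation). Without wild-type library 1 or 4 or ACP7 OE library 1 this list gave adjusted p = 0.061, 0.057 and 0.19. The riser was ugt-64 (log2 fold change 1.12, SE 0.07, adjusted p = 3.3e-11).

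The other lists did not pass as lists. skr-4 of the pathogen response list had an adjusted p of 0.036, lost without any of 9 libraries. icl-1, of the glyoxylate cycle, in the list of DAF-16 targets, fell by 0.45 on the log2 scale (adjusted p = 0.0083). fasn-1, fatty acid synthase, had an adjusted p of 0.024, or 0.069, 0.11 and 0.053 without wild-type library 3, ACP7 OE library 3 or ACP7 OE library 4. No member passed among 6 vitellogenin, 12 p38 immune, 16 glutathione and oxidative defence, 20 ER and 10 mitochondrial unfolded protein response, 28 lipid breakdown, 22 one-carbon and propionate, 140 collagen, 17 intestine, 83 ribosomal protein or 35 histone genes. Adjusted over the list alone, 1 one-carbon gene was higher and 2 lower, and 2 histone genes were higher and 1 lower. The medians of the collagen and insulin-like lists (-0.03 and -0.07) had the opposite sign to their means (0.19 and 0.38) and to their tests. The count of 422 became 794 without wild-type library 5, 256 without ACP7 OE library 3, 651 without ACP7-7A OE library 2, and 2434 without ACP7-7A OE libraries 1 and 2 and wild-type library 5. The balance of higher and lower genes depended on the setting. It turned to 113 higher and 151 lower with a filter of 50 reads in 5 libraries, 290 and 504 without wild-type library 5, 193 and 224 without ACP7 OE library 1, 175 and 205 without ACP7 OE library 5, and 1021 and 1413 without those 3 libraries. With a surrogate variable it was 826 and 332. When library labels were exchanged, 14 of 100 splits, the real one included, gave at least as many lists as the 15 found, so chance is not excluded for that number of lists. The other splits had a median of 9 lists.

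**Figure D2:**
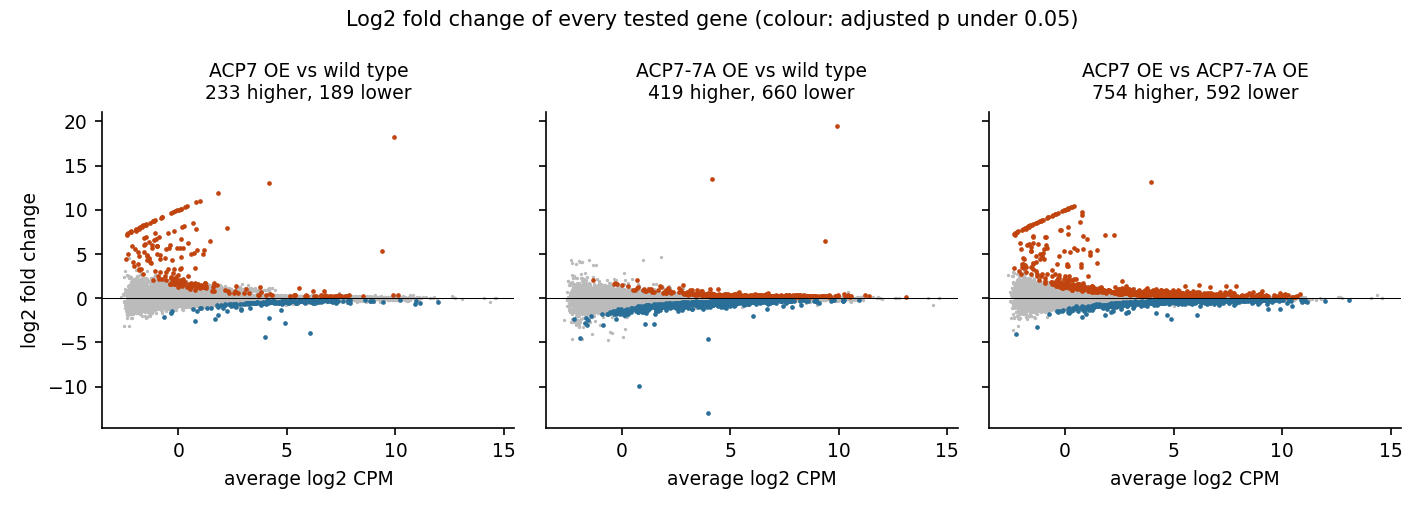
Log2 fold change (vertical axis) against average log2 CPM (horizontal axis) of the 15725 genes tested, in each comparison, with genes past the threshold in red where higher, in blue where lower and the others in grey. The counts are 233 and 189, 419 and 660, and 754 and 592, and the higher genes of ACP7 OE against either group include many at low average levels, where fitted values of genes at 0 in a group depend on the prior count.

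Against wild type, ACP7-7A OE animals lacked transcripts of T21C9.6 and ttr-23, which lie next to each other on chromosome V. T21C9.6 (10581887 to 10587077, plus strand) had 22.9 ± 3.04 CPM in wild type, 24.4 ± 4.76 CPM in ACP7 OE and 0 counts in ACP7-7A OE, at least 1760-fold lower than wild type. ttr-23, which encodes a transthyretin-like protein (10589092 to 10589860), had 0 counts in ACP7-7A OE, at least 214-fold lower. The eggshell genes perm-2, perm-4 and cpg-1 rose, by log2 fold changes of 0.33, 0.45 and 0.37 (adjusted p = 0.0018, 0.00012 and 0.0023). The protease gene cpr-4 fell by 1.00 on the log2 scale (SE 0.08, adjusted p = 7.9e-08).

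In this comparison 1079 of 15725 genes changed, 419 higher and 660 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). An absolute log2 fold change of at least 1 was reached by 22 of the higher and 109 of the lower genes. Of the higher genes, rnh-1.3, an RNase H gene (chromosome I, 9710088 to 9710745), rose 2.89-fold from 4.36 ± 0.317 CPM (adjusted p = 3.2e-08), H11L12.1 from 11.9 ± 0.963 to 24.7 ± 2.74 CPM (adjusted p = 1.2e-06) and Y57G7A.8 from 2.02 ± 0.299 to 5.49 ± 0.855 CPM (adjusted p = 4.2e-05). B0024.4, enu-3.4 and C06A5.12 rose 2.41-, 2.29- and 2.04-fold, and C06A5.12 overlaps C06A5.2 on the other strand. Of the lower genes, C38D9.2 and C38D9.13, which were also lower in ACP7 OE, fell 4.07-fold and 2.62-fold (adjusted p = 4.2e-15 and 0.0013). F53F1.6 fell 7.57-fold (adjusted p = 0.00017), bath-25 3.53-fold, Y37A1B.7 3.06-fold, arrd-24 2.97-fold, cyn-17 2.82-fold, C05C12.4 2.80-fold and sdz-24 2.47-fold.

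Of 30 germline and oocyte genes, 14 rose and 16 did not pass (23 higher adjusted over the list alone), with list adjusted p = 6.6e-13, or adjusted p = 0.80 with an estimated correlation. The medians of this list were 9.41 and 9.47 log2 CPM in ACP7-7A OE libraries 1 and 2, 9.15 to 9.22 in libraries 3 to 5, and 9.25 in wild-type library 5 against 8.97 to 9.07 in the other wild-type libraries. Of 19 lysosomal and digestive proteases, 9 fell, including asp-13, cpr-3 and cpz-1 (log2 fold changes -0.31, -0.52 and -0.28, adjusted p = 0.0043, 0.0059 and 0.0093), and 10 did not pass (11 lower adjusted over the list alone; list adjusted p = 3.1e-08, or adjusted p = 0.80 with an estimated correlation). Of 17 intestine genes, ges-1 and ifd-2, an intermediate filament gene (log2 fold change -0.80, SE 0.13, adjusted p = 0.0015), fell and 15 did not pass (11 lower adjusted over the list alone; list adjusted p = 4e-05, or adjusted p = 0.80 with an estimated correlation). The median log2 fold changes of the protease and intestine lists were -0.22 and -0.24. The intestine medians were 5.28 and 5.45 log2 CPM in ACP7-7A OE libraries 1 and 2, 5.56 to 5.70 in libraries 3 to 5, and 5.36 in wild-type library 5 against 5.98 to 6.18 in the other wild-type libraries.

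Of 50 transthyretin-like genes 4 fell, among them ttr-46 (log2 fold change -0.39, SE 0.07, adjusted p = 0.0016), and 46 did not pass (list adjusted p = 0.0064, or adjusted p = 0.80 with an estimated correlation). The mean of this list was -0.31, or -0.27 with ttr-23 at its bound, and the median -0.12 either way. Of 119 cytochrome P450 and UDP-glucuronosyltransferase genes, 10 fell and 109 did not pass (13 lower adjusted over the list alone; list adjusted p = 0.0098, or adjusted p = 0.80 with an estimated correlation). cyp-35A2 fell by 0.95 and cyp-33C9 by 0.43 on the log2 scale (adjusted p = 0.0015 and 0.0073). Of 14 molting genes, 4 fell and 10 did not pass (5 lower adjusted over the list alone; list adjusted p = 0.012, or adjusted p = 0.80 with an estimated correlation). mlt-8 fell by 0.51 on the log2 scale (adjusted p = 0.014).

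The remaining lists did not pass as lists. Of the lysozymes, C-type lectins and saposin-like proteins, 3 rose, 21 fell and 152 did not pass, with spp-5 and clec-56 falling by 0.45 and 0.52 on the log2 scale (adjusted p = 0.0015 and 0.0014). Of 12 p38 immune genes 2 rose, 1 fell and 9 did not pass. sysm-1 rose by a log2 fold change of 0.82 (adjusted p = 0.0030) and irg-4 fell by 0.68 (adjusted p = 0.0087). The other riser, clec-85, had an adjusted p of 0.041, lost without any of 12 libraries. gst-38, a glutathione S-transferase gene, rose by a log2 fold change of 1.13 (adjusted p = 0.0014), skr-4 fell by 0.54 (adjusted p = 0.0049), hsp-43 fell by 0.41 (adjusted p = 0.0029) and ins-19 fell by 2.86 (adjusted p = 0.014). acdh-1 and hach-1, of propionate breakdown, fell by 0.29 and 0.25 (adjusted p = 0.0057 and 0.0048). Of 140 collagen genes 1 rose and 6 fell, with dpy-7 falling by 0.77 (adjusted p = 0.0035), and of 12 mitochondrially encoded genes ND1 rose by 0.29 while ND5 fell by 0.34 (adjusted p = 0.0035 and 0.0019). Of 85 sperm genes 1 passed, spe-41, lost without any of 11 libraries. Of 20 basement membrane genes 3 passed, lower, and of 83 ribosomal protein genes 1 higher and 3 lower. No member passed among the vitellogenin, mitochondrial unfolded protein response, early embryo, body wall muscle, pharynx, neuron and histone lists.

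The medians of the collagen, insulin-like, heat shock, fatty acid synthesis, glutathione and histone lists (-0.12, 0.04, 0.06, -0.04, -0.02 and -0.01) had the opposite sign to their means (0.05, -0.02, -0.06, 0.03, 0.09 and 0.10). The count of 1079 became 2248 without wild-type library 5, 503, 449, 402 and 489 without wild-type libraries 1, 2, 3 and 4, 588 and 707 without ACP7-7A OE libraries 2 and 3, and 1747 without ACP7-7A OE libraries 1 and 2 and wild-type library 5. Without ACP7 OE library 3 there were 548 higher and 510 lower genes. As many lists as the 6 found were given by 71 of 100 splits of the libraries, the real one included, so chance is not excluded for that number. The other splits had a median of 7 lists, above the 6 found.

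ACP7 OE was also compared with ACP7-7A OE, which differs in phosphatase activity by design, in the dose of the construct as measured, and in strain. A single strain carries each construct, so the 3 cannot be told apart here. Lysosomal and digestive proteases were higher in ACP7 OE, with 11 of 19 rising, 0 falling and 8 not passing (14 higher adjusted over the list alone). cpr-4 was higher by a log2 fold change of 1.39 (SE 0.08, adjusted p = 2.2e-10), asp-13 by 0.57 (adjusted p = 9.1e-07), the cathepsin B-like cpr-6 by 0.42 (adjusted p = 5.5e-05) and the cathepsin Z-like cpz-1 by 0.39 (adjusted p = 0.00019). The list gave adjusted p = 1.6e-16 with the preset correlation and adjusted p = 0.084 with an estimated correlation. Its median log2 fold change was 0.36, and that of the intestine list was 0.30, with all 17 members positive. The lysozyme gene lys-4 (chromosome IV, 11621429 to 11623174) was 2.89-fold higher in ACP7 OE than in ACP7-7A OE (log2 fold change 1.53, SE 0.18, adjusted p = 0.00018), and ugt-64 was higher by a log2 fold change of 1.39 (SE 0.07, adjusted p = 7.8e-13).

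Between the constructs 1346 of 15725 genes changed, 754 higher and 592 lower in ACP7 OE (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). An absolute log2 fold change of at least 1 was reached by 246 of the higher and 54 of the lower genes, and 129 of the higher genes averaged under 1 CPM over all libraries. T21C9.6 was at least 1840-fold higher in ACP7 OE. clec-197, F59B2.12, F26D2.16, Y51A2D.8 and try-8, near 0 in wild type, were near 0 in ACP7-7A OE as well (0.0649 ± 0.123, 0.0911 ± 0.158, 0.171 ± 0.141, 0.163 ± 0.257 and 0.204 ± 0.197 CPM). ins-19, F53F1.6 and C05C12.4 were 15.3-, 5.75- and 3.79-fold higher. Of the lower genes, F56A4.3 was 5.24-fold, C38D9.2 3.80-fold, T22B7.7 3.79-fold, dhs-26 3.62-fold and F15D4.5 3.23-fold lower. rnh-1.3, clec-209, F56A4.2, nspc-4 and amt-1 were lower by 3.19-, 2.98-, 2.86-, 2.85- and 2.68-fold.

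Of the lysozymes, C-type lectins and saposin-like proteins, 55 of 176 were higher in ACP7 OE, 6 lower and 115 did not pass (65 and 7 adjusted over the list alone), with list adjusted p = 4e-17, or adjusted p = 0.013 with an estimated correlation. The list's median was 0.38, and its mean 1.17, or 1.08 with its 7 members at 0 in ACP7-7A OE or ACP7 OE set to their bound. clec-99 was higher by a log2 fold change of 5.44 (SE 0.49, adjusted p = 5.6e-08). Of 17 intestine genes, 5 were higher and 12 did not pass (12 higher adjusted over the list alone), ifd-2 by a log2 fold change of 0.76, ges-1 by 0.35 and spl-1 by 0.26 (list adjusted p = 3.2e-06, or adjusted p = 0.42 with an estimated correlation). Of 10 heat shock genes, 4 were higher, hsp-70 by 1.22 and hsp-16.2 by 2.17 (adjusted p = 0.00051 and 0.0015; list adjusted p = 0.021, or adjusted p = 0.20 with an estimated correlation). skr-4 of the pathogen response list was higher by 0.95 (adjusted p = 2.7e-06; list adjusted p = 0.021, or adjusted p = 0.36 with an estimated correlation), and that list's call was lost without any of 10 libraries.

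Mitochondrially encoded genes were lower in ACP7 OE, with 6 of 12 lower, 1 higher and 5 not passing, ND1 by a log2 fold change of -0.65 and ATP6 of -0.48 (list adjusted p = 3.9e-07, or adjusted p = 0.23 with an estimated correlation). Here too the list may reflect RNA preparation, which was not tested. Of 10 mitochondrial unfolded protein response genes 4 were lower, among them hsp-6, a mitochondrial chaperone gene (log2 fold change -0.19, SE 0.05, adjusted p = 0.020; list adjusted p = 0.012, or adjusted p = 0.23 with an estimated correlation). Of 30 germline and oocyte genes, 5 were lower and 25 did not pass, perm-4 by a log2 fold change of -0.53 (adjusted p = 3.3e-06; list adjusted p = 8.6e-05, or adjusted p = 0.68 with an estimated correlation), and without ACP7-7A OE libraries 1 and 2 and wild-type library 5 that list gave adjusted p = 0.13. Of 20 basement membrane genes, 6 were lower and 1 higher, with lam-1 at -0.33 and lam-2 at -0.32 (list adjusted p = 0.0050, or adjusted p = 0.63 with an estimated correlation). Of 14 early embryo genes 2 were lower and 12 did not pass, vet-6 by a log2 fold change of -0.82 (adjusted p = 0.0026) and sdz-28 by -0.85 (adjusted p = 0.024, lost without any of 5 libraries; list adjusted p = 0.00091, or adjusted p = 0.20 with an estimated correlation), and the list gave adjusted p = 0.054 without those 3 libraries. Of 16 body wall muscle genes 15 did not pass and unc-89 was lower (log2 fold change -0.75, adjusted p = 0.013; list adjusted p = 0.0032, or adjusted p = 0.74 with an estimated correlation). The libraries of ACP7-7A OE differed here, with muscle medians of 7.69 and 7.90 log2 CPM in libraries 1 and 2, below the 8.10 to 8.36 of ACP7 OE, and 8.45 to 8.58 in libraries 3 to 5. unc-89 had 127 and 134 CPM in libraries 1 and 2, 181 to 198 CPM in libraries 3 to 5, and 81.2 to 136 CPM in ACP7 OE.

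Of 85 sperm genes, 4 were higher, 1 lower and 80 did not pass, with nspd-9 higher by a log2 fold change of 2.05 (adjusted p = 0.0056; list adjusted p = 1.6e-08, or adjusted p = 0.63 with an estimated correlation). The sperm-list medians were 1.04 and 0.93 log2 CPM in ACP7-7A OE libraries 1 and 2, 2.57 to 2.80 in libraries 3 to 5, and 2.61 to 3.37 in ACP7 OE libraries. Without ACP7-7A OE libraries 1 and 2 and wild-type library 5, left out after seeing the data, the median log2 fold change of the list was 0.19 in place of 0.73 (adjusted p = 0.036). Of 83 ribosomal protein genes, 9 were higher (list adjusted p = 0.020, or adjusted p = 0.78 with an estimated correlation), and that list gave adjusted p = 0.37 without ACP7 OE library 1, 0.050 without ACP7-7A OE library 1 and 0.12 without ACP7-7A OE library 3. The other lists did not pass as lists. pho-11 and pho-14 were lower by log2 fold changes of -0.50 and -0.49 (adjusted p = 9.2e-06 and 9.1e-05), sysm-1 by -0.71, gst-7 by -0.26, dnj-27 by -0.32 and his-24 by -0.52. fat-6, a stearoyl-CoA desaturase gene, was higher by 0.27 (adjusted p = 0.0044), lipl-5 by 0.31, ech-6 by 0.20, acdh-1 by 0.34, hach-1 by 0.42, nas-37 by 0.56, ttr-46 by 0.43 and ins-31 by 7.07, while acdh-7 was lower by -0.31. Of 140 collagen genes 3 were higher and 2 lower, with col-43 and col-158 at -1.28 and -1.21 and dpy-7 at 0.65. No member passed among the vitellogenin, DAF-16, pharynx and neuron lists. The acid phosphatase, insulin-like and histone lists had medians of 0.01, -0.02 and -0.02 with means of -0.04, 0.40 and 0.00.

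The count of 1346 became 1901 without ACP7 OE library 1, 883 without ACP7 OE library 4, and 2212 without ACP7-7A OE libraries 1 and 2 and wild-type library 5, with 1085 higher and 1127 lower. As many lists as the 13 found were given by 17 of 100 splits of the libraries, the real one included, so chance is not excluded for that number. The other splits had a median of 8 lists.

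**Figure D3:**
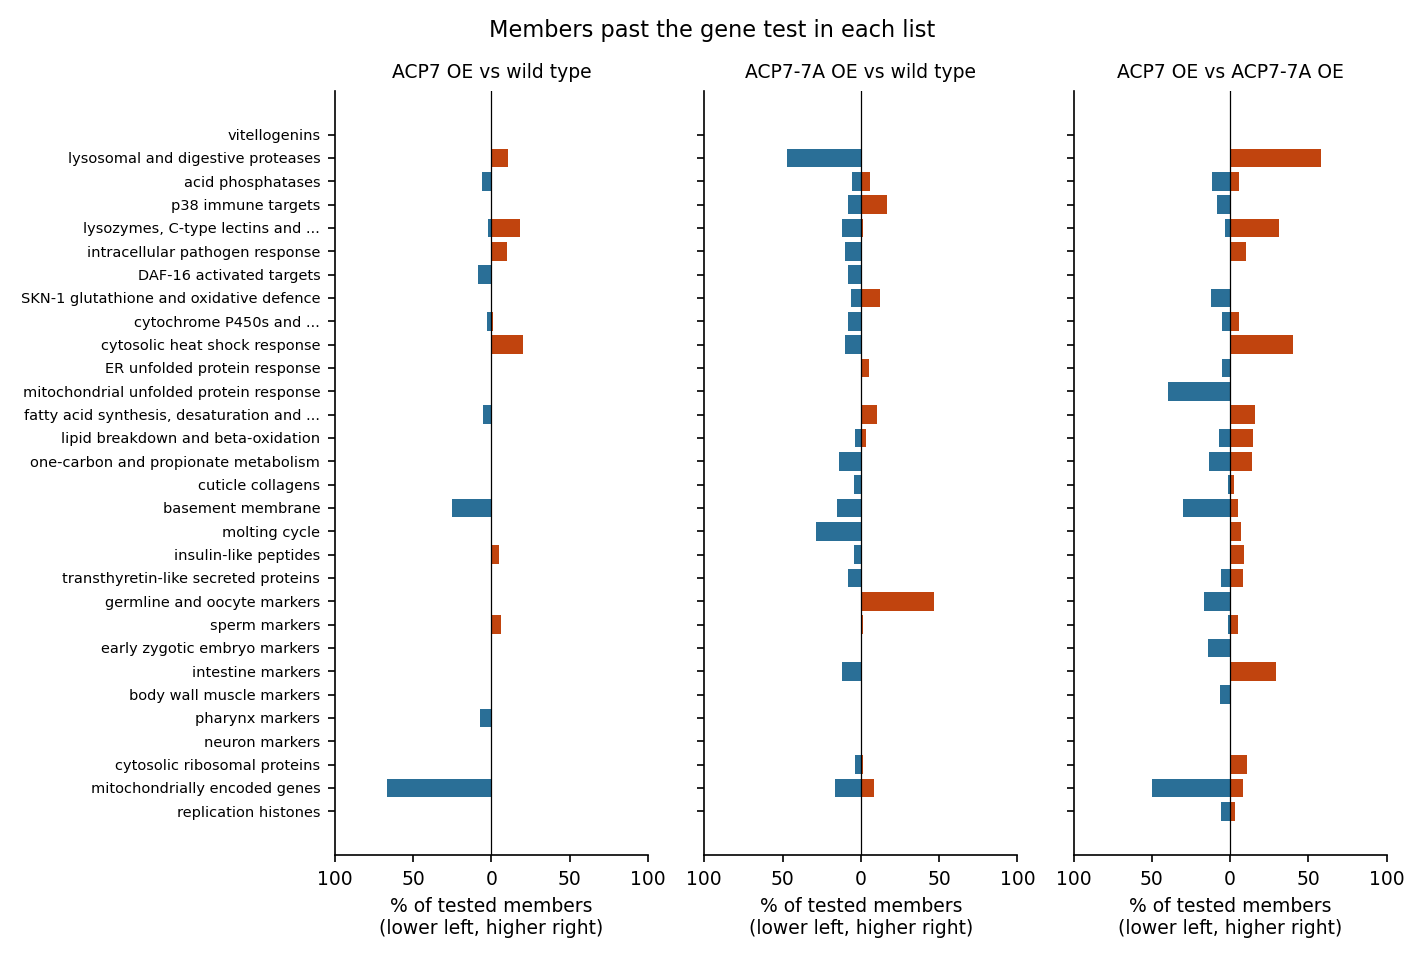
Share of the tested members of each of the 30 lists (horizontal axis, percent) that were higher (red, to the right) or lower (blue, to the left) past the gene test in each comparison. Mitochondrially encoded genes, a list planned as a sign of RNA preparation, are lower in 8 of 12 members in ACP7 OE against wild type. Lysosomal and digestive proteases are higher in 11 of 19 in ACP7 OE against ACP7-7A OE.

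Genes that set ACP7 OE apart from both other groups numbered 255, 159 higher and 96 lower. Lists of the same sizes drawn independently would share 11.2 and 7.12 genes. Simulated unchanged groups shared 0. No gene was changed in them, so they had little to share and do not show what lists of these sizes would share. With the ACP7 OE libraries split so that the comparisons shared none, the median over 20 splits was 130 (116 to 144), from shorter lists (medians of 199 and 585 genes) that would share 4.17 if independent. The balance turned to 74 higher and 83 lower with a filter of 50 reads in 5 libraries, and to 269 and 588 without ACP7-7A OE libraries 1 and 2 and wild-type library 5. K12H6.4 (chromosome II, 2823707 to 2824269, minus strand) had 3.82 ± 0.70 CPM in ACP7 OE and 0 counts in ACP7-7A OE, at least 293-fold higher. Its neighbour K12H6.9 (2824404 to 2824957, plus strand), at 3.4 ± 0.736 CPM in ACP7 OE, was at least 264-fold higher, and whether the 2 genes share reads was not examined. clec-137 was at least 276-fold, clec-207 at least 247-fold and tag-329 at least 239-fold higher. clec-137 overlaps pqn-35 on the other strand. irld-35, between F56A4.3 and F56A4.2, was among the shared lower genes (log2 fold change between the constructs -2.07, SE 0.38, adjusted p = 0.00085).

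Genes that set ACP7-7A OE apart from both other groups numbered 485, 172 higher and 313 lower, among them rnh-1.3, T21C9.6 and cpr-4. The higher genes include F21A3.11 and WormScarlet, which the construct itself carries. Independent lists would share 15.8 and 31.6. Simulated unchanged groups shared 0, but with no gene changed they had little to share. Splits of the ACP7-7A OE libraries gave a median of 79.5 (29 to 298), from lists with medians of 220 and 664 genes. Such lists would share 5.82 if independent (1.54 to 206). The count became 781 without wild-type library 5 and 231 without wild-type library 3. It was 285, 239 and 266 without wild-type libraries 1, 2 and 4, 322 without ACP7 OE library 4, and 289 and 299 without ACP7-7A OE libraries 2 and 3.

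Genes changed the same way in both overexpression groups against wild type numbered 61, 17 higher and 44 lower, among them fbxa-195, C38D9.2 and C38D9.13, and 13 genes changed in opposite directions, among them cpr-4. The higher genes include F21A3.11 and WormScarlet, which the constructs themselves carry. They also include fbxa-195, which lies beside ges-1, the source of the promoter. The overlaps below were not computed without these genes. Independent lists would share 6.21 and 7.93. Simulated unchanged groups shared 0, but with no gene changed they had little to share. Splits of the wild-type libraries gave a median of 11 (7 to 13), from shorter lists (medians of 188 and 209 genes). Such lists would share 1.02 if independent (0.319 to 6.84). The count became 282 without wild-type library 5. With a surrogate variable 96 were higher and 56 lower, and without ACP7-7A OE libraries 1 and 2 and wild-type library 5 there were 285 and 316. It was 26, 33, 28 and 29 without wild-type libraries 1 to 4 and 40 and 29 without ACP7 OE libraries 2 and 3.

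Across all 15725 genes, which are not independent replicates, the log2 fold changes of ACP7 OE and ACP7-7A OE against wild type had a Pearson r of 0.371 and a Spearman rho of 0.421. Simulated unchanged groups that shared the wild-type libraries gave means of 0.504 and 0.449. The covariance was 0.149, against 0.050 in the simulation. The simulation drew each gene independently and held no library that stood apart from its group. It therefore does not show what unchanged groups of libraries like these would give, and a value above or below it decides nothing about the constructs. With wild-type libraries split the medians were 0.238 for r, 0.212 for rho and 0.118 for the covariance. The sign was the same for 66.8% of genes, and for 66.6% in the simulation. The standing of r against the simulated value depended on the genes used. Without F21A3.11 and WormScarlet r was 0.332 (simulated 0.504) with a covariance of 0.124 (simulated 0.050), while over the 10570 genes with an average log2 CPM of at least 1 it was 0.623 (simulated 0.507) with a covariance of 0.0919 (simulated 0.0126). Both of these sets of genes were chosen after seeing the data.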

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

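The tests of 3 patterns in this part were chosen only after the results had been seen, while the exchanges of library labels were fixed in advance. Dixon's test at a critical ratio of 0.71 was applied to 559 groups of 5 libraries, over named genes and library measures, and 55 had a library far from the other 4. The ratio is the gap to the nearest library over the range of the 5. Far thus means far for the spread of the group, and the difference itself can be small. For rps-24, ACP7 OE library 1 had 1254 CPM, against 1221 to 1226 CPM in the other ACP7 OE libraries. Chance alone would give 27.9, about 1 group in 20, and genes that move together add to the number. Of the 55, 21 fell on wild-type library 5 and 18 on ACP7 OE library 1.

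In wild-type library 5 the genes far above the other wild-type libraries were C38D9.2 (ratio 0.822), dhs-26 (0.817), T22B7.7 (0.807), gst-7 (0.749), hsp-6 (0.848), pgl-3 (0.824), pgl-1 (0.724) and cpg-1 (0.861). Those far below were sdz-24 (0.765), lys-4 (0.807), clec-56 (0.753), skr-4 (0.715), cyp-13A5 (0.787), dhs-28 (0.711), nid-1 (0.805), ttr-16 (0.821), ifo-1 (0.740), tni-1 (0.717), myo-2 (0.771) and ND1 (0.762). This library also had the fewest genes with a count in its group, 17612 (0.718). In ACP7 OE library 1 the genes far above the other ACP7 OE libraries were unc-54 (0.771), H11L12.1 (0.778), gst-7 (0.849), hsp-3 (0.920), pdi-1 (0.752), acs-13 (0.756), acdh-7 (0.791), pcca-1 (0.861), pccb-1 (0.716), dgn-1 (0.826), let-2 (0.727), pgl-1 (0.712), perm-4 (0.734), perm-2 (0.721), cpg-1 (0.861), mex-5 (0.720), myo-1 (0.863) and rps-24 (0.855).

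In ACP7-7A OE library 1, dnj-27 (0.818) and dpy-7 (0.833) were far above the rest of the group and pho-11 (0.731), fasn-1 (0.834) and nas-37 (0.788) far below. Library 2 stood above for lys-4 (0.782) and mlt-11 (0.711), library 4 above for hpo-8 (0.731) and below for dpy-2 (0.736), library 3 below for pho-14 (0.769) and library 5 below for B0024.4 (0.723). ACP7 OE library 2 stood above for enu-3.4 (0.727) and below for ddr-2 (0.775) and spe-18 (0.800), and ACP7 OE library 5 above for vet-6 (0.878). Wild-type library 2 stood below for cyp-14A4 (0.770).

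A group of 97 genes, clec-197 and try-8 among them, stood near 0 outside ACP7 OE, with summed levels of 134 to 271 CPM in ACP7 OE libraries and 2.17 to 6.19 CPM in the others. Males or male tissue could contribute, since a separate list of 13 male genes, none of them in the group, summed to 2.92 ± 0.805 CPM in ACP7 OE against 1.5 ± 0.302 and 1.72 ± 0.715 CPM (exact one-sided permutation p = 0.00266 over 3003 splits). That test leaves this cause open. More of the sperm that the sperm list measures was argued against as the whole cause, because the list's medians overlapped between groups. The lowest ACP7 OE median, 2.61 (SD 0.28, n = 5), less the highest of the other libraries, 2.80, was -0.19. The genes were chosen for a log2 fold change of at least 3. The list has 0 members in the group and was expressed in every group. It therefore cannot decide whether the group holds other transcripts of sperm that are near 0 outside ACP7 OE. A change at 1 chromosome was argued against too, because the chromosome with the most of these genes held 30.9% of them.

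Libraries 1 and 2 of ACP7-7A OE and library 5 of wild type stood apart within their groups in sperm, collagen and germline genes. Depth was argued against, with 44.8 as the lower of the totals of ACP7-7A OE libraries 1 and 2 in units of 1e6 counts, between 41.7 and 48.6 in libraries 3 to 5. The rRNA share was argued against as well, with 1.237% in library 2 and 2.136% in library 1 on either side of 1.241% to 1.842%. Timing at collection remains open, because the sperm-list median of wild-type library 5, 1.62 against 2.09 to 2.2 in its group, is part of what set it apart and does not test timing.

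T21C9.6 and ttr-23, the genes at 0 in ACP7-7A OE among those at 2 CPM or more in wild type, lie next to each other, and chance placing was argued against (share 0.0008 of 10000 draws). No reads were examined for a deletion in that strain. In ACP7 OE, 22 genes lower by a log2 fold change of at least 1 against wild type held 5 pairs within 20 kb. In 1000 random draws of tested genes there were 3 at most. The pairs were F15D4.5 with F15D4.6, C38D9.2 with C38D9.13, and those among F56A4.3, irld-35 and F56A4.2, so they are not 5 separate places. The draws did not allow for related genes lying together. A strain difference at these places remains open, and neighbours regulated together or copies that share reads would give the same.

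Few exchanges of library labels gave as many changed genes as the real groups. Such exchanges cannot separate a construct from its strain or from anything else that goes with the label. Libraries within a group also differed from each other, so they are not fully exchangeable. In ACP7 OE against wild type 1 of 100 splits, the real one, gave as many genes (422, highest other 86), and between the constructs 1 of 100 (1346, highest other 601). In ACP7-7A OE against wild type 3 of 100 gave as many (1079, highest other 2248), and that highest split, wild-type libraries 1 to 4 with ACP7-7A OE library 5, points to a structure of the samples. Chance could not be excluded for the numbers of lists, with 14, 71 and 17 of 100 splits giving as many in the 3 comparisons (real 15, 6 and 13, highest other 21, 18 and 18). The medians of the other splits were 9, 7 and 8 lists. The list test with the preset correlation thus passed several lists under exchanged labels too. Of the regroupings of all libraries 1 of 100 each gave as many shared genes, for ACP7 OE against both others (255, highest other 0), ACP7-7A OE against both (485, highest other 48) and both against wild type (61, highest other 0). The other regroupings had a median of 0 shared genes, so this does not show that changed genes were shared beyond chance, and comparisons that share libraries also share errors.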

How the results depend on the processing

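The values with 3 libraries left out (ACP7-7A OE 1 and 2 and wild type 5), with every count halved, and over other sets of genes were chosen only after the results had been seen. No called named gene or list changed direction. Of the lists that did not pass, fry gave the opposite direction for the heat shock and body wall muscle lists in ACP7-7A OE against wild type and the molting list between the constructs. Between the constructs the collagen list, which did not pass, passed with a positive median with a surrogate variable and with a negative one without the 3 libraries. Of the calls of named genes 69 were lost in at least 1 run with a library left out, 14 in fits of the compared groups alone, 13 without the 3 libraries, 12 with upper-quartile scaling, 9 without a filter, 8 with a surrogate variable, 8 with the stricter filter, 4 with limma-voom, 1 with RLE scaling, 1 with library sizes without mitochondrial, rRNA and histone genes, 0 with DESeq2 and 0 with counts halved. Of the calls of lists 9 were lost and 12 gained in at least 1 run with a library left out, 8 lost and 7 gained with a surrogate variable, 5 lost and 15 gained without the 3 libraries, 32 lost with an estimated correlation and 17 with fry for direction, 0 lost and 2 gained with the block, and 0 lost or gained in fits of the compared groups alone. Under scaling or tests the median over all genes moved by 0.011 at most. The cause was not tested for the changes below, apart from the stricter thresholds, which call fewer genes by construction.

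In ACP7 OE against wild type the count of 422 became 264 with a filter of 50 reads in 5 libraries, 723 with DESeq2, 1182 in a fit of the compared groups alone, 1158 with a surrogate variable, 2434 without ACP7-7A OE libraries 1 and 2 and wild-type library 5, 187 at adjusted p under 0.01 and 206 with an absolute log2 fold change of at least 1. In ACP7-7A OE against wild type 1079 became 1724 with DESeq2, 1747 without those 3 libraries, 240 at adjusted p under 0.01 and 131 with the fold threshold. Between the constructs 1346 became 2917 with a surrogate variable, 2212 without the 3 libraries, 608 at adjusted p under 0.01 and 300 with the fold threshold.

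The 255 genes that set ACP7 OE apart became 157 with the stricter filter, 747 with a surrogate variable and 857 without the 3 libraries. The 485 that set ACP7-7A OE apart became 757 without the 3 libraries. The 61 changed in both against wild type became 127 with DESeq2, 152 with a surrogate variable and 601 without the 3 libraries. The correlation of 0.371 became 0.238 with wild-type libraries split and 0.623 over genes at an average log2 CPM of at least 1, rho became 0.212 with the split, and the covariance of 0.149 became 0.217 without the 3 libraries.

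Past the threshold with an estimated correlation were 1, 0 and 1 lists in place of 15, 6 and 13, with fry for direction 6, 3 and 8, and with fry for change in either direction 17, 20 and 24. Without the 3 libraries 11 lists passed in ACP7-7A OE against wild type. With each library left out in turn, the counts of genes ran from 256 to 794, 402 to 2248 and 883 to 1901, the shared counts from 192 to 321, 231 to 781 and 26 to 282, and the lists from 11 to 16, 6 to 11 and 12 to 15. The correlation ran from 0.281 to 0.407, rho from 0.351 to 0.501 and the covariance from 0.129 to 0.188.

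No pairing by replicate number was seen: correlations between libraries of the same number ran from -0.37 to 0.20, with 3 of 15 pairs over 0.1. In 1 of the 15 pairs the library of the same number was the best match. A shared culture or day with little effect on these values would not show here. With the replicate number as a block the counts were 289, 633 and 1035, the shared counts 208, 300 and 29, and 36 of the named calls were lost. With every count halved the counts of genes were 409, 1150 and 1368, and no lower depth was tested.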

Other observations

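All values below, on the X chromosome, unc-54, fbxa-195, cwp-1 and R08F11.4, were chosen only after the results had been seen. Genes on the X chromosome were frequent among those lower in ACP7 OE, 52 of 181 lower nuclear genes against 10 of 232 higher ones. The X chromosome held 14.3% of tested nuclear genes and 28.7% of the lower ones (Fisher p = 4.77e-07, with genes treated as independent). Medians were taken only over nuclear genes with an average log2 CPM of at least 1. The median log2 fold change in ACP7 OE was -0.14 on the X chromosome and 0.01 on autosomes, and in ACP7-7A OE -0.10 and 0.03.

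The ratio of unc-54 to unc-15, another muscle gene, was 1.83 ± 0.0747 in wild type, 2.03 ± 0.0881 in ACP7 OE and 2.47 ± 0.126 in ACP7-7A OE (SD, n = 5 each). Against wild type the exact permutation p was 0.0159 for ACP7 OE and 0.00794 for ACP7-7A OE. fbxa-195 was lower in ACP7 OE than in ACP7-7A OE by a log2 fold change of -0.43 (SE 0.10), and its log2 fold change less that of WormScarlet was 0.79 (SE 0.15). cwp-1, a male neuron gene, had counts in 4 ACP7 OE libraries and in 0 others.

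R08F11.4 (chromosome V, 3803839 to 3805527) had 43.3 ± 23.6 CPM in wild type, 2.04 ± 0.432 CPM in ACP7 OE and 1.75 ± 0.673 CPM in ACP7-7A OE. The wild-type libraries were not alike: libraries 1 to 4 had 53.3 to 55.1 CPM and library 5 had 1.08 CPM, inside the 1.01 to 2.72 CPM of the ACP7-7A OE libraries. Its log2 fold changes against wild type were -4.41 (adjusted p = 0.0055) and -4.63 (adjusted p = 0.0047).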
